A study of Mus musculus with 2 samples.

How the data were processed

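Skin of 3-day-old C57BL/6 mice was sequenced by the submitters in 2 libraries, 1 for the wildtype and 1 for the RNF31fl/fl-K14-cre genotype, per the labels. Tissue was ground and RNA extracted with TRIzol, and libraries were made with a directional kit, per the labels' protocols. Whether strand was used in counting, and the number of animals behind each library, are not given in the sources used here. Groups were taken from the genotype labels.

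The tools named in the submitters' processing notes are cutadapt 1.9.1, HISAT2 2.0.4 and Cufflinks 2.2.1, with the build GRCm38. The annotation release and the handling of reads shared between genes are not given in the sources used here. The main deposited table has the column set of a Cuffdiff comparison, per the file headers, and holds 1 abundance per gene and library in FPKM, which the authors computed as fragments per kilobase of transcript, scaled by library depth. It also holds the p-value and q-value of the authors' own comparison of the 2 libraries, per the file headers. A small deposited sheet names HISAT2 for alignment, Cuffdiff for abundance and GRCm38 as reference, and gives the number of reads and the fraction of reads aligned for each library. The sheet does not state whether its reads are single reads or pairs. The authors' log2 ratio and test statistic columns were not used, because the first holds spreadsheet error text for many genes. A total of 26 symbols that a spreadsheet had turned into dates were restored from their gene identifiers. Of 44166 gene identifiers, 43831 were found in the gene name table and in GENCODE mouse release 21, which gave positions in GRCm38, written 1-based.

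Depth was 19619928 reads for the library labelled WT (18160205 aligned) and 20511407 for the library labelled KO (19196626 aligned). Low FPKM values of genes with a single transcript of at least 3000 bases lay near whole multiples of a common step. Within 0.25 of a whole step lay 88.8% of 285 values for the library labelled WT and 83.7% of 295 for the library labelled KO, where 50% would by chance. That step was used to estimate fragments per gene from FPKM and the longest transcript. Exact binomial (Clopper-Pearson) 95% intervals of the ratio between the libraries come from these estimated fragments. They cover counting error at most. They can be too narrow even for that, since reads without molecular identifiers are not independent molecules and the fragments are estimates. An exact 0 in the deposited FPKM can be a failed estimate, so such genes are described as listed at 0 and have no fold.

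The measure throughout was log2 of (FPKM + 1) in the library labelled KO over (FPKM + 1) in the library labelled WT, on the deposited scale. The pseudocount of 1 understates the difference of low genes, and ratios given beside it are of FPKM without pseudocount. Genes with an FPKM of at least 1 in at least 1 library entered (14541). A gene counted as higher or lower when the measure was at least 1 or at most -1, a 2-fold difference. With 1 library per genotype there is no replicate spread, so no p-value between genotypes was computed and no difference has a replicate check.

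The lists, the measure, the floor, the 2-fold rule, the naming rule and 9 alternative settings were chosen before the data were examined. Named genes are the 15 genes with the highest and the 15 with the lowest log2 ratio among genes above the floor. Predicted genes (Gm with digits, or symbols ending in Rik), mitochondrial and ribosomal protein genes were left out of these 2 sets. Further named genes are members of each list past the 2-fold rule and up to 4 of its members with the largest absolute log2 ratio, the 10 most abundant genes of each library, and 15 genes always reported. The last are Rnf31, Rbck1, Sharpin, Krt14, Krt5, Krt1, Krt10, Lor, Flg, Ivl, Tnf, Tnfrsf1a, Casp8, Ripk3 and Mlkl. A few genes outside this rule are named after their values were seen, namely Irf9 for its overlap with Rnf31, members that stayed inside the 2-fold rule or under the floor, and those of the closing observations. Some genes that the rule takes are not reported here.

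There were 38 lists with 588 symbols. They cover the linear ubiquitin machinery, TNF receptor and death signalling, apoptosis and pyroptosis executors, NF-kB targets, proinflammatory cytokines, chemokines, interferon-stimulated genes, and antimicrobial and alarmin genes. Epidermal and skin structure lists are stress and activation keratins, basal keratinocyte, spinous keratinocyte, granular layer and cornified envelope, epidermal barrier lipid metabolism, tight junction and adhesion, hair follicle and hair keratins, sebaceous gland, proliferation, fibroblast and extracellular matrix, and matrix proteases and wound repair. Cell type lists are adipocyte, skeletal muscle, neutrophil, macrophage and monocyte, dendritic and Langerhans cell, T cell and innate lymphocyte, B cell, mast cell with eosinophil and basophil, erythroid, endothelial, melanocyte, Schwann cell and nerve, and chondrocyte and bone. Lists on sample state are immediate early genes, hypoxia and glycolysis, fatty acid oxidation and thermogenesis, mitochondrially encoded genes, housekeeping genes and sex-linked genes. Of the symbols, 4 were unmatched (Krt85, Hbb-b1, Hbb-b2 and Ahsp) and 4 were matched through a synonym or current symbol. Each list median is given with its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression.

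The counting script was tested on simulated data, 20 pairs of libraries of 14513 genes drawn at the estimated depth for this comparison. Per pair, a mean of 5.3 unchanged genes passed the 2-fold rule. Changed genes were drawn only from those with a mean FPKM of at least 5 over the 2 libraries, so recovery at lower levels was not tested. Of these, genes changed 3-fold were recovered in 99.95% (raised) and 99.15% (lowered) of cases, and genes changed 8-fold in 100%. The list percentiles were tried on 200 lists of 15 genes drawn at random, with the observed log2 ratios. Of unshifted lists 4% lay outside the central 95%, and all lists shifted by 1 on the log2 scale were found. The first share follows from the construction and does not cover lists of genes that vary together. The alternatives were pseudocounts of 0.1 and 5, 3 other scalings, no floor or a floor of 5, a log2 size rule of 2, and means in place of list medians. Leaving out genes listed at 0, leaving out near-identical gene families, and a rescaling without the 50 most abundant genes that kept the mean level were added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.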

Results

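Whole skin of 3-day-old C57BL/6 mice was profiled by RNA sequencing in 2 genotypes, wildtype and RNF31fl/fl-K14-cre, with 1 library each. Rnf31 encodes HOIP, the catalytic subunit of the linear ubiquitin chain assembly complex, and K14-cre is a recombinase driven by the keratin 14 promoter, which is active in basal keratinocytes and passes to the cells that descend from them. The comparison asked which transcripts differed in level in neonatal skin when Rnf31 was targeted in keratinocytes. The library labelled WT had 19619928 reads, of which 92.56% aligned, and the library labelled KO had 20511407 reads, of which 93.59% aligned. There were no replicates, so every difference described here is between 2 libraries, without a test between genotypes, and values are given as higher or lower. The deposited table listed 44166 genes in FPKM, and 14541 of them reached an FPKM of 1 in at least 1 library. At this depth an FPKM of 1 over a 2 kb transcript corresponded to about 31.0 fragments in the library labelled WT and 31.6 in the library labelled KO. Intervals on ratios are exact binomial 95% intervals on estimated fragments, cover counting error at most, and leave out variation between animals.

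Rnf31 itself was not lower in the library labelled KO. Its FPKM was 3.95 in the library labelled WT and 5.4 in the library labelled KO, a ratio of 1.36 (95% counting interval 1.18 to 1.59) and a log2 ratio of 0.37. The gene (ENSMUSG00000047098, chromosome 14, 55591708 to 55603693 in GRCm38) was thus slightly higher, not lower, in the library whose label names its deletion, and the label of each library is for that reason written as a label throughout. A gene-level value sums all exons and all cell types of the skin, and the position of the loxP sites is not given in the sources used here. The 3' end of Rnf31 also shares 123 bases with the interferon-stimulated gene Irf9, whose FPKM was 6.91 and 15.1 in the libraries labelled WT and KO, so that reads of one can be counted for the other. The partner subunits of the complex were close to equal, with Rbck1 (HOIL-1) at 44.3 and 41.5 (ratio 0.936, 0.873 to 1.004) and Sharpin at 20.4 and 22.4 (ratio 1.1, 0.979 to 1.22). None of the 9 measured members of the list of the complex and its regulators differed 2-fold. The list median log2 ratio was 0.13, at percentile 88.4 of 10000 random lists of matched expression, with Tnfaip3 (A20) at -0.17, Otulin at 0.14 and Spata2 at -0.13.

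Differences of the skin labelled KO from the skin labelled WT included higher levels of wound-type keratins, cornified envelope precursors and inflammatory mediators. Hair shaft keratins and pigment cell genes were among those at lower levels. Of the 14541 genes, 1103 (7.59%) were at least 2-fold higher and 595 (4.09%) at least 2-fold lower in the library labelled KO on the log2(FPKM + 1) scale, so that 65.0% of the large differences were higher. With FPKM rescaled after leaving out the 50 most abundant genes the counts were 1133 and 1054 (51.8% higher), and the median log2 ratio of all genes shifted by -0.12 from its value of -0.08. That setting also enlarged FPKM against the pseudocount, and with the mean level kept the counts were 953 and 794 (54.6% higher, shift -0.11). Scaling by the median of ratios gave 1244 and 502 (71.2% higher, shift 0.09), so the balance of higher and lower genes depends on the scaling. The correlation of log2(FPKM + 1) between the libraries was r = 0.914 across genes, which are not independent replicates. Keratin 6b, a keratin of wounded epidermis, had the largest log2 ratio (10.12), with an FPKM of 1.64 in the library labelled WT and 2935 in the library labelled KO. The 15 largest log2 ratios included 5 genes of the late cornified envelope 3 group (Lce3a, Lce3b, Lce3d, Lce3e, Lce3f), 6 small proline-rich genes (Sprr1b, Sprr2d, Sprr2e, Sprr2f, Sprr2g, Sprr2i), Krt16, the alarmin S100a9 and the beta-defensin Defb14. Of these 15, 5 were listed at 0 in the library labelled WT, namely Lce3a, Lce3d, Sprr2f, Sprr2i and Defb14, and no fold is given for them. Lce3, Sprr2, beta-defensin and stefin genes have near-identical copies, and Krt6b is close in sequence to Krt6a. The split of reads among such copies is uncertain, and the ratio of Krt6b with it.

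Among the 15 lowest log2 ratios were the retinol transporter gene Stra6 (17.5 against 1.82 in the library labelled KO), the retinol-binding protein gene Rbp7 (30.6 against 4.77), the melanocyte channel gene Trpm1 (67.8 against 13.2) and the hair keratin Krt35 (616 against 113). The transcription factor genes Dlx4 (-2.47) and Msx1 (-2.25), the metallothionein Mt4 (-2.27), the peptide transporter gene Slc15a2 (-2.40), and Dapl1 (-2.36), Serpina3b (-2.74), Fam117a (-2.34), Wnk4 (-2.28) and Gnmt (-2.24) were in the same set. The remaining 2, CH25-309J2.1 and Tma7-ps, were listed at 0 in the library labelled KO and at 103 and 11 in the library labelled WT. Both are very short (chromosome 9, 13519936 to 13520101, and chromosome 1, 171711088 to 171711282), so their FPKM rests on few bases and is uncertain. In the library labelled WT, 8 of the 10 most abundant transcripts were from ribosomal protein genes, led by Rpl41 (11852), Rplp1 (8765) and Rpl13a (8065), and the others were mt-Atp8 and mt-Nd1. In the library labelled KO, Krt14 was the most abundant of all (12590.1), and Krtdap (7013), Lgals7 (6288), the stefin-family gene BC100530 (4599.6) and Krt16 (4552) were also among the 10 most abundant, beside 4 ribosomal protein genes.

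**Figure D1:**
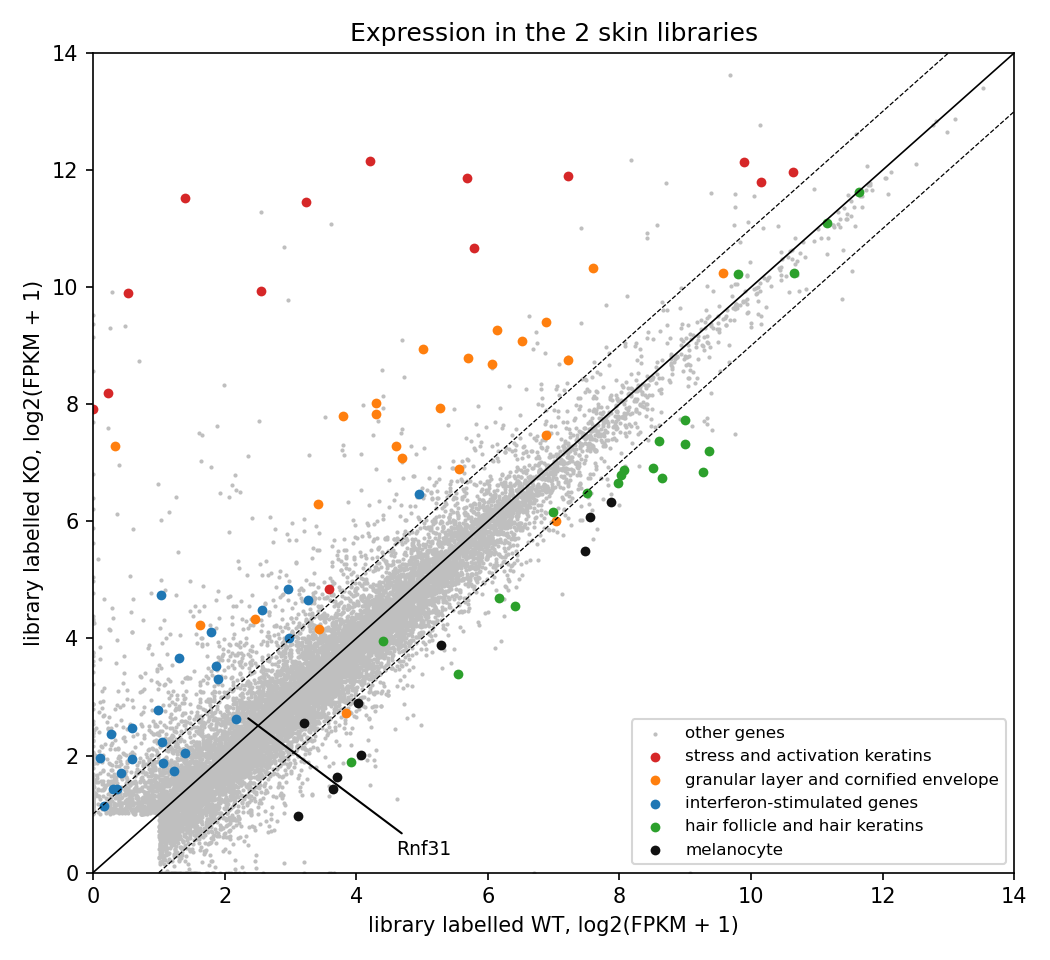
Each point is 1 of the 14541 genes with an FPKM of at least 1 in a library, at log2(FPKM + 1) in the library labelled WT (x axis) and in the library labelled KO (y axis), with members of 5 gene lists coloured, equality as a solid line and 2-fold differences as dashed lines. Stress keratin and cornified envelope genes lie above the upper dashed line in most cases (14 of 14 and 19 of 24), hair and melanocyte genes mostly below the lower (15 of 21 and 9 of 10), and Rnf31 lies between the lines with a log2 ratio of 0.37.

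The list of stress and activation keratins, with other genes of activated epidermis, had the largest median of the 38 lists. All 14 measured stress and activation genes were higher in the library labelled KO, with a median log2 ratio of 6.78 (percentile 100, and 6.19 without genes listed at 0). Krt6a was 50.3 in the library labelled WT and 3745 in the library labelled KO, Krt16 was 17.4 and 4552 (ratio 261, 237 to 288), and Sprr1b was 8.43 and 2792. The smallest difference of the list was in Il1rn, the interleukin 1 receptor antagonist gene (11 and 27.6). Together these genes made up 0.59% of the FPKM sum in the library labelled WT and 4.58% in the library labelled KO. Of 24 granular layer and cornified envelope genes, 19 were higher and 2 lower (Flg2 and Lce1m), with a median of 2.62 (percentile 100). Repetin (Rptn) was 0.257 and 156 in the libraries labelled WT and KO, and involucrin (Ivl) was 9.67 and 77.3 (ratio 7.99, 7.06 to 9.05). The 2 major structural proteins of the normal cornified layer differed less, with loricrin (Lor) at 758 and 1213 (ratio 1.6) and filaggrin (Flg) at 117 and 176 (ratio 1.5). The Lce1 genes of this list have close copies and are uncertain one by one.

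Many of the envelope genes are neighbours in the genome. The epidermal differentiation complex on chromosome 3, which holds the genes for cornified envelope precursors, contributed the 1 Mb window with the most higher genes. In the window from 92000001 to 93000000, 43 of 47 genes above the floor were higher in the library labelled KO and 0 were lower past the 2-fold rule, with a median log2 ratio of 3.85. Lor and 3 other genes there were inside the rule.

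**Figure D2:**
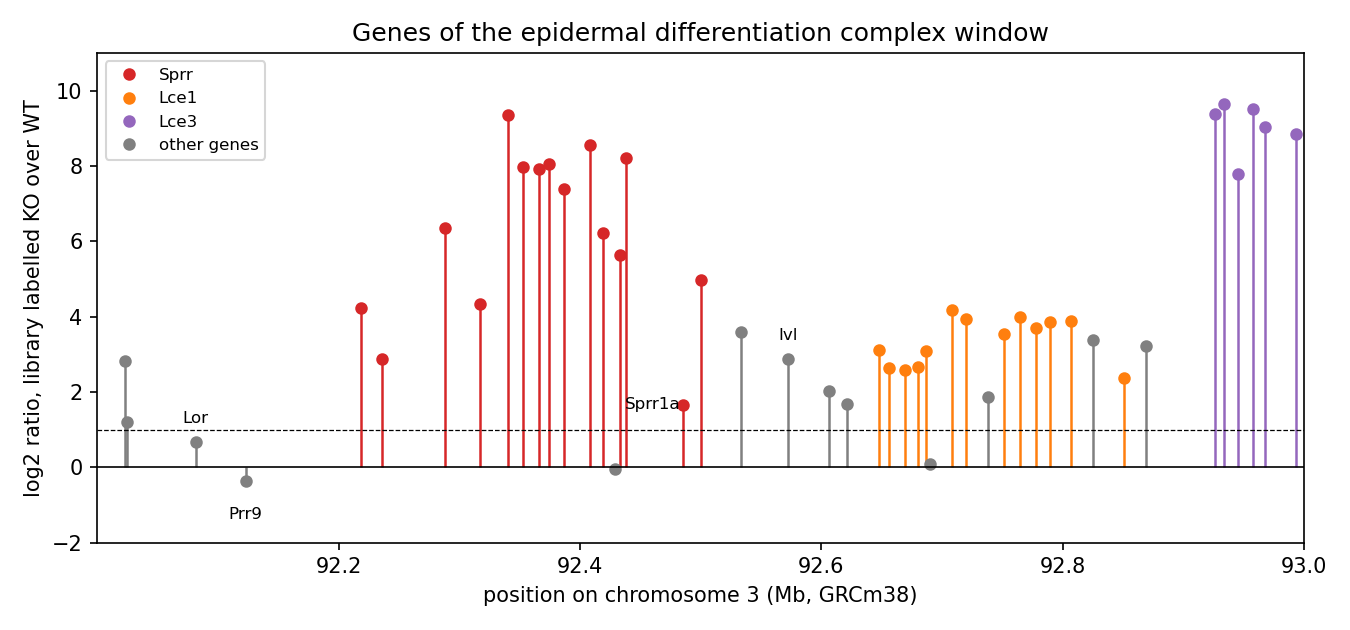
Log2 ratio of FPKM + 1, library labelled KO over library labelled WT, for the 47 genes above the floor between positions 92000001 and 93000000 of chromosome 3 in GRCm38, each drawn as a stem at the middle of the gene and coloured by gene family. The Lce3 stems stand between 7.79 and 9.64, the Lce1 stems between 2.38 and 4.18, and Lor is at 0.68, below the dashed line of 2-fold difference.

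Markers of the living epidermal layers did not differ by a common factor. Of 12 basal keratinocyte genes 9 were higher and 1 lower, with a median of 1.61 (percentile 100). Krt14 was 816 in the library labelled WT and 12590.1 in the library labelled KO (ratio 15.4, 15.2 to 15.6), while its pairing partner Krt5 had a ratio of 2.86 (2.82 to 2.89) and the basal and bulge keratin Krt15 was lower (226 and 97.1). Krt14 is similar in sequence to Krt16 and Krt17, and how shared reads were divided is not given in the sources used here. The basement membrane adhesion genes Col17a1 and Itga6 had ratios of 4.16 and 3.75. Of 12 spinous keratinocyte genes 5 were higher and 1 lower, with a median of 0.75 (percentile 99.97). The secreted differentiation products Krtdap, Sbsn and Dmkn were higher (ratios 6.26, 5.37 and 3.58), whereas the main spinous keratin Krt10 was lower (678 and 188, ratio 0.278, 0.27 to 0.286) and Krt1 had a ratio of 0.762. Of 16 barrier lipid genes 9 were higher and 0 lower (median 1.42, percentile 100), led by the lipoxygenase Alox12b (1.45 and 43.6), the fatty acid elongase Elovl4 (43.8 and 241) and the lipid transporter Abca12 (2.16 and 15). Of 12 tight junction and adhesion genes, Dsc2 and Dsg3 were higher (ratios 5.23 and 3.88) and 10 were inside the 2-fold rule, and the median was 0.16 (percentile 94.7).

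Most measured cytokine, chemokine and antimicrobial genes were higher in the library labelled KO. Of 10 measured proinflammatory cytokine genes 8 were higher and 0 lower, with a median of 3.98 (percentile 100). Il33, an alarmin cytokine, was 0.528 and 57.8 (ratio 109, 70.9 to 176). The genes of interleukin 36 alpha and gamma, listed as Il1f6 and Il1f9, were 1.24 and 70.9, and 1.4 and 84.2. Il24 was listed at 0 in the library labelled WT and at 18.8 in the library labelled KO. Tslp, an epithelial cytokine of allergic inflammation, was 0.195 and 16.7. Tnf (0.316 and 1.26, ratio 3.98, 1.84 to 10.2) and Il1a (ratio 2.28, 1.42 to 3.59) had ratios above 2 and were inside the 2-fold rule only through the pseudocount. The remaining 12 cytokine genes of the list, among them Il17a, Il22 and Ifng, stayed under an FPKM of 1 in both libraries, and with them included the median was 0.58. Of 19 chemokine genes 14 were higher and 0 lower (median 2.45, percentile 100), among them Cxcl5 (0.0534 and 40), Ccl8 (2.46 and 120.1) and the interferon-inducible Cxcl10 (0.0772 and 11.5). Of 14 antimicrobial and alarmin genes 11 were higher and 0 lower (median 4.63, percentile 100, and 3.36 without genes listed at 0). S100a8 was 11.2 and 2149.8, S100a9 was 4.88 and 2489.5, and the beta-defensins Defb14 and Defb4 were listed at 0 in the library labelled WT and at 565 and 112 in the library labelled KO.

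Of 18 genes known as targets of NF-kB, the transcription factor activated through linear ubiquitin chains, 9 were higher and 0 lower, with a median of 1.14 (percentile 100). Members differed in size, with Cxcl1 at 0.295 and 7.6, Ccl2 at 1.05 and 10.2 and Nfkbia at 36.4 and 90.2, and with Tnfaip3, Sod2 and Traf1 at log2 ratios of -0.17, -0.20 and -0.47. The list shares 6 measured members with other lists, 4 of them chemokines, and its other 12 members had a median of 0.81, with 5 higher and 0 lower. Of 24 interferon-stimulated genes 19 were higher and 0 lower, and the median was 1.40 (percentile 100). Examples are the guanylate-binding protein gene Gbp2 (1.04 and 25.8), Gbp3 (1.48 and 11.8), Ifit3 (2.46 and 16.2) and Oasl1 (0.202 and 4.19). Irf9 is a member too and is uncertain because of its overlap with Rnf31.

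Genes of death receptor signalling differed less than their inflammatory neighbours. Of 16 members 3 were higher and 0 lower, and the median was 0.42 (percentile 99.8). The 3 are the nucleic acid sensor gene Zbp1 (1.24 and 15.9, ratio 12.8, 9.92 to 16.8), the kinase gene Ripk3 (6.1 and 15.2, ratio 2.48, 2.09 to 2.96) and Mlkl, the gene of the membrane-disrupting effector (1.4 and 4.29, ratio 3.05, 2.15 to 4.37). Casp8 had a ratio of 1.35 (1.14 to 1.6) and the TNF receptor 1 gene Tnfrsf1a of 1.39 (1.31 to 1.46), both inside the 2-fold rule. Tnfrsf1b (ratio 2.54, 1.96 to 3.29) and Tnf were inside it only through the pseudocount. Of 16 apoptosis and pyroptosis genes, Pmaip1 (NOXA) and the inflammatory caspase gene Casp4 were higher (ratios 3.97 and 4.17), 0 were lower, and the median was -0.23 (percentile 14.9).

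Most measured markers of macrophages, monocytes and neutrophils were higher beside these inflammatory lists. Of 17 macrophage and monocyte genes 14 were higher and 0 lower (median 1.45, percentile 100), with the inflammatory monocyte marker Ly6c2 at 0.111 and 5.37, Fcgr3 at 8.38 and 30.9, and the complement gene C1qb at 54.5 and 152. Of 11 neutrophil genes 9 were higher and 0 lower (median 1.56, percentile 100), with Retnlg and Ngp listed at 0 in the library labelled WT and at 26.2 and 6.37 in the library labelled KO. In that list 6 members are held by another list too, and S100a8 and S100a9 are also made by activated keratinocytes. The 5 members of the neutrophil list alone had a median of 1.55, with 4 higher and 0 lower. Of 10 mast cell, eosinophil and basophil genes 4 were higher and 0 lower (median 0.82, percentile 99.8), such as the tryptase gene Tpsab1 (0.64 and 9.2) and Hdc (4.16 and 22.5). The 7 measured dendritic and Langerhans cell genes had a median of 0.19 (percentile 91.7), with Batf3 higher (1.32 and 7.56). Lymphocyte markers were sparse. Of 22 T cell and innate lymphocyte genes 5 were measured, with 2 higher (Trbc2 at 17.3 and 76.5, and Trbc1) and 1 lower (Gata3 at 86.3 and 39.5). Their median of 0.12 (percentile 79.2) turned to -0.01 with the 50 most abundant genes left out of the scaling. That median is the value of Thy1, which the fibroblast list holds too, and the other 4 members, Gata3 among them, had a median of 0.56. With most of the list under an FPKM of 1, Gata3 at 86.3 need not come from lymphocytes. Of 8 B cell genes, Ighm alone was measured and was lower (3.0 and 0.325, log2 ratio -1.60, percentile 1.88).

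Hair follicle and pigment cell transcripts were lower in the library labelled KO. Of 21 hair follicle and hair keratin genes 15 were lower and 0 higher, with a median of -1.26 (percentile 0). Krt35 and Krt83, keratins of the hair shaft, had ratios of 0.184 (0.178 to 0.19) and 0.223 (0.216 to 0.231). Lef1, a transcription factor of the hair matrix, was 45.8 and 9.49, and the follicle signal gene Shh was 14.1 and 2.7. Of 10 melanocyte genes 9 were lower and 0 higher, and the median was -1.76 (percentile 0). The pigment enzyme gene Tyr was 11.5 and 1.68 (ratio 0.146, 0.123 to 0.173), and Oca2, Mc1r and Slc45a2 had ratios of 0.125, 0.19 and 0.175. None of 20 proliferation genes differed 2-fold, but 19 of them lay below 0, with a median of -0.53 (percentile 0). Among them were Tyms (25 and 12.7), Ccna2 (39.6 and 21.6) and Mki67 (25 and 13.7, ratio 0.549, 0.521 to 0.579). Of 12 sebaceous gland genes 3 were higher and 0 lower (median 0.40, percentile 99.5), namely the wax synthase genes Awat1 (2.1 and 15) and Awat2, and Plin2.

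Most fibroblast matrix genes were inside the 2-fold rule, and most matrix protease and wound repair genes were higher in the library labelled KO. Of 20 fibroblast and extracellular matrix genes, Tnc, the gene of the wound-associated tenascin C, was higher (16.8 and 61.9), and 19 were inside the 2-fold rule. The list median was -0.16 (percentile 17.4), with Col1a1 at 1022 and 666 (ratio 0.651). Of 17 matrix protease and wound repair genes 12 were higher and 0 lower (median 1.30, percentile 100), and 2 of them, Mmp8 and Mmp9, are also in the neutrophil list. These included the growth factor gene Hbegf (3.19 and 55.6, ratio 17.4, 14.7 to 20.8), Mmp9 (0.0687 and 5.67) and Timp1 (9.58 and 44.8). Of 15 adipocyte genes 1 was higher and 2 lower, with a median of -0.57 (percentile 0.04). The adipokine genes Lep (4.72 and 1.27) and Adipoq (169 and 75.7) were lower, and Cidea was higher (3.82 and 19.1). Of 18 skeletal muscle genes 5 were higher and 2 lower (median 0.32, percentile 99.8), with the myosin genes Myh2 at 2.16 and 14 and Myh1 at 42.2 and 102. Whole skin can carry differing amounts of the muscle and fat beneath it.

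Of 14 endothelial genes, Selp and Lyve1 were higher (ratios 6.31 and 2.63) and Cldn5 lower (0.401), and the median was 0.17 (percentile 93.7). The 9 Schwann cell and nerve genes had a median of 0.13 (percentile 86.8), with Mbp higher (2.34) and S100b and Sox10 lower (0.20 and 0.422). The 6 measured erythroid genes all lay below 0 without passing the 2-fold rule (median -0.65, percentile 0.3), with Alas2 at 14 and 8.01 and the near-identical Hba-a1 and Hba-a2 uncertain one by one. Of 4 chondrocyte and bone genes Alpl was lower (4.78 and 1.37), and the median was -0.78 (percentile 0.79).

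Several lists that follow stress, metabolism and sample handling differed as well. Of 18 immediate early genes 8 were higher and 1 lower (median 0.72, percentile 100). Fos was 6.68 and 54.3, Fosl1 0.792 and 13.3, and Dusp1 7.5 and 50.6, while Egr3 was the lower one. Of 14 hypoxia and glycolysis genes 3 were higher and 0 lower (median 0.70, percentile 100), with the glucose transporter gene Slc2a1 at 8.19 and 65.1 (ratio 7.95, 7.18 to 8.83). Of 12 fatty acid oxidation and thermogenesis genes 3 were higher and 0 lower (median 0.38, percentile 99.6), among them Cidea and Pdk4 (5.65 and 24.1). The 10 mitochondrially encoded genes had a median of -0.16 (percentile 27.2), with 0 past the 2-fold rule. Among 14 housekeeping genes B2m, which is also induced by interferon, was higher (147 and 448) and 13 were inside the rule. Their median of 0.13 (percentile 94.2) became -0.00045 with the 50 most abundant genes left out of the scaling. Of the sex-linked genes, Ddx3y (17.5 and 16.4), Eif2s3y, Kdm5d and Uty were present in both libraries and Xist was under the floor in both. Their median was -0.07 (percentile 50.8), and its sign differed between scalings.

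**Figure D3:**
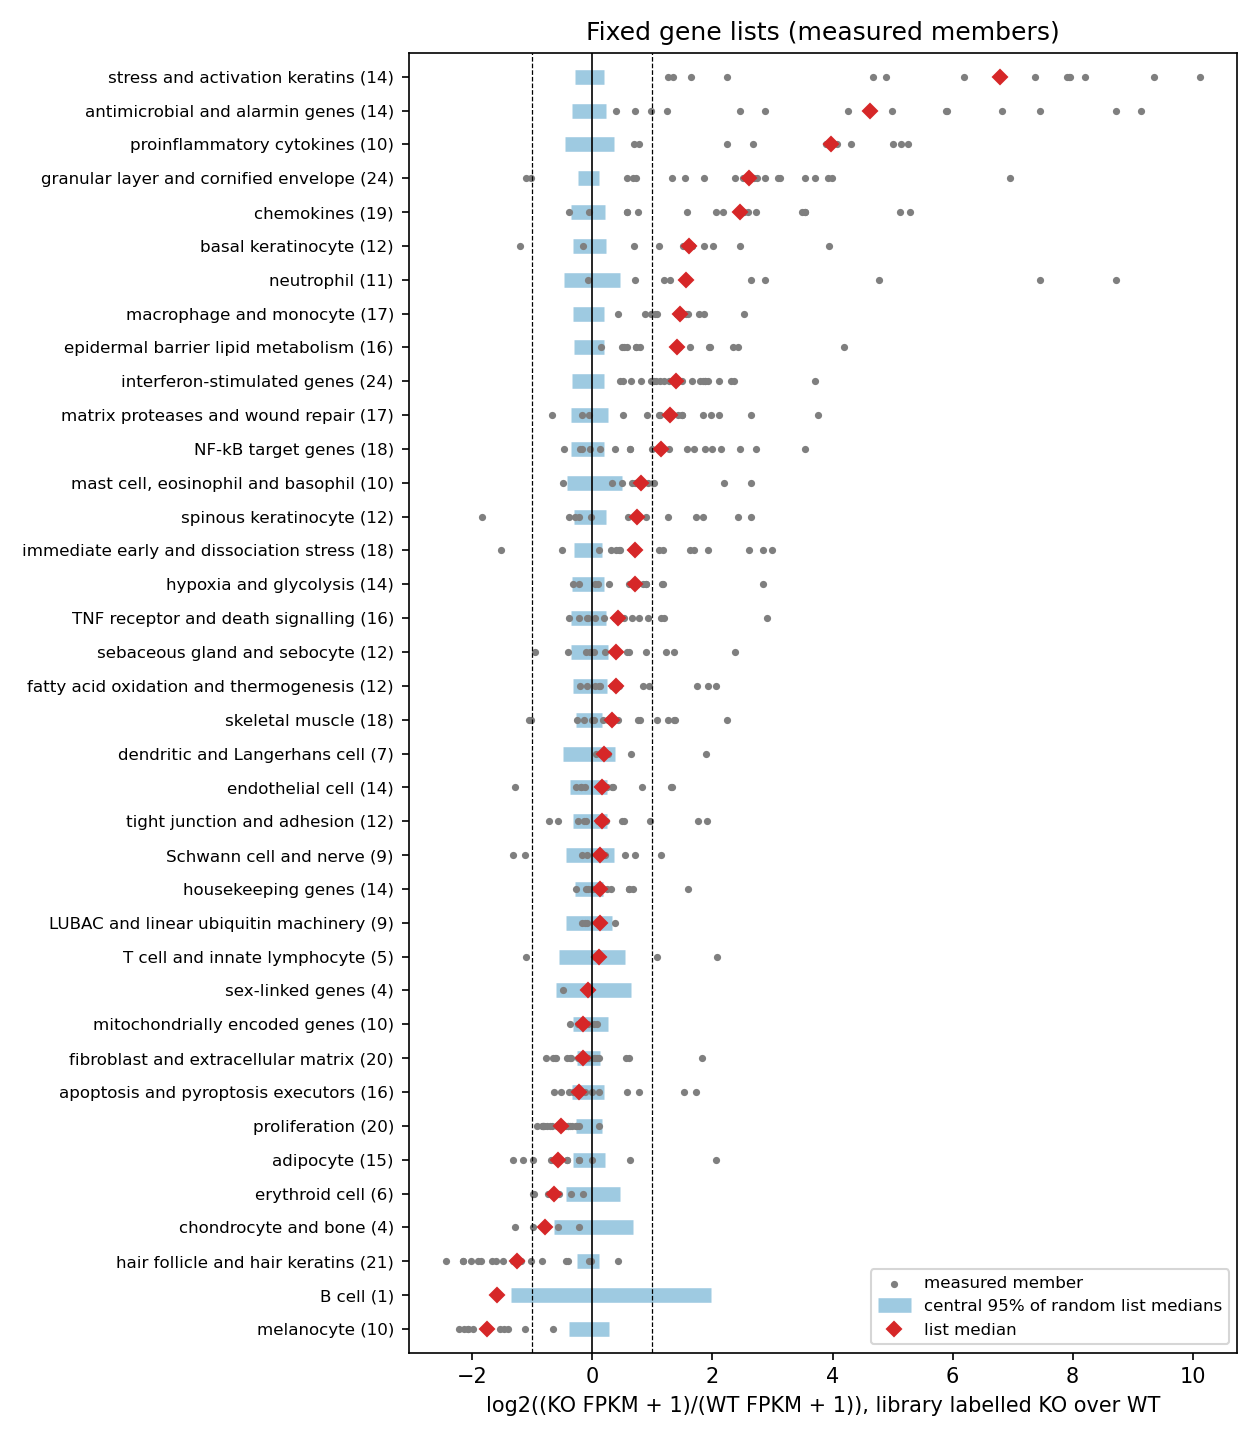
Log2 ratios of FPKM + 1, library labelled KO over library labelled WT, for the measured members (grey points) of the 38 gene lists, with the list median (red diamond) and the central 95% of the medians of 10000 expression-matched random lists (blue bar), 0 as a solid line and 2-fold differences as dashed lines. The medians run from -1.76 for melanocyte genes to 6.78 for stress and activation keratins, with 20 lists above their bar, 7 below and 11 inside.

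Across the 38 lists, 20 medians lay above and 7 below the central 95% of random lists and 11 lay inside. If the genes of each list were drawn at random, 1.9 lists outside would arise by chance. Lists share members and genes of a tissue vary together, so these percentiles describe the 2 libraries and are not tests. All directions given here follow the library labels, which the value of Rnf31 does not bear out.

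According to the authors' deposited table, 96 genes were called different, 92 of them higher and 4 lower in the library labelled KO, from a comparison of 1 library with 1 library. In the authors' deposited table the q-values of these calls ran from 0.0120 to 0.0487, and Krt14 had q = 0.0282. The 4 genes called lower in the authors' deposited table were Tyr, Trpm1, Stra6 and Skint9, the last of them listed at 0 in the library labelled KO. The calls in the authors' deposited table included 12 Lce genes, 6 Sprr2 genes and 4 beta-defensin genes. Rnf31 had p = 0.679 and q = 0.999 in the authors' deposited table. Krt6b (q = 0.0530) and S100a9 (q = 0.0902) were not called in the authors' deposited table.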

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

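The alternatives without genes listed at 0, without near-identical families and with the mean level kept were chosen after the results were seen. No paired analysis was possible because each genotype had 1 library. No list median outside the central 95% of random lists, and no named gene past the 2-fold rule, reversed its direction under any alternative run on it. For the named genes this outcome was fixed in advance and is no sign of robustness. A pseudocount cannot change the sign of a log2 ratio, and the other scalings shifted the median of all genes only by -0.12 to 0.09. List medians outside the central 95% could hardly reverse under these settings either, since the smallest in size was 0.32 (skeletal muscle). Only the changes of floor, the means and leaving out genes listed at 0 left room for a list to reverse. Of 379 recomputed list values, 356 stayed within 1.5-fold of the reported value, and of 1134 recomputed values of 189 named genes 152 did not, 51 of them at a pseudocount of 0.1 and 79 at a pseudocount of 5. Rnf31 stayed between 0.22 and 0.45 on the log2 scale under 6 alternatives.

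With a pseudocount of 0.1, 1085 genes were lower, and the medians were 5.52 for cytokines, 4.08 for chemokines, 2.15 for interferon-stimulated, 5.91 for antimicrobial, 4.08 for neutrophil, -2.87 for B cell and 1.42 for mast cell genes. With a pseudocount of 5, 528 genes were higher and 165 lower, and the medians were 2.16, 1.03, 0.77 and 3.59 for the first 4 of these lists, 5.73 for stress keratins, 0.60 for matrix proteases and -0.59 for B cell genes. These shifts follow from the construction, since low values weigh more with a small pseudocount. Rescaling without the 50 most abundant genes gave 1054 lower genes. With the mean level kept there were 794, so part of that count came from the weight of the pseudocount. An FPKM floor of 5 left 10150 genes with 360 lower, and a neutrophil median of 2.88. A log2 size rule of 2 left 297 higher and 49 lower genes. Without a floor the medians were 0.58 for cytokines, 3.57 for antimicrobial, 6.19 for stress keratin and -0.0030 for B cell genes, because members near 0 entered. Means in place of medians gave 5.79 for stress keratins and 2.97 for neutrophil genes. Without genes listed at 0 the medians were 3.36 for antimicrobial and 6.19 for stress keratin genes. Depth limits statements on genes near an FPKM of 1, where about 31.0 fragments stand behind a 2 kb transcript.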

Other observations

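The gene families and genes in the first 2 paragraphs, and all tests given here except those of counting noise, Irf9 reads and the Krtap family, were chosen after the results were seen. Some of these families share members with the fixed lists. Of 13 guanylate-binding protein and immunity-related GTPase genes, which act in interferon-induced defence, 12 were higher and 0 lower in the library labelled KO, with a median log2 ratio of 2.27. Gbp2 and Gbp3 are also in the interferon-stimulated list, and the other 11 had a median of 2.16. Iigp1 was 1.05 in the library labelled WT and 31.1 in the library labelled KO (ratio 29.7, 22.3 to 39.8). Of 11 major histocompatibility class I genes 9 were higher and 0 lower (median 1.46), with H2-K1 at 79.2 and 317 and H2-D1 at 108 and 256, although copies of this family are hard to tell apart. Of 10 kallikrein protease genes 9 were higher and 0 lower (median 3.32, and 3.61 without Klk5 and Klk7 of the granular layer list), and Klk6 was 6.78 and 874 (ratio 129, 109 to 152). The acute phase gene Saa3 was 0.169 and 192, and Serpinb2 was 3.34 and 97.4. In the interleukin 1 family the receptor antagonist gene Il1f5 was higher (13 and 139), while Il1f10 was lower (9.0 and 1.51).

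The cellular retinoid-binding protein genes Rbp2 (25.4 and 352) and Crabp2 (15.7 and 142) were higher in the library labelled KO, with ratios of 13.8 (12.3 to 15.6) and 9.0 (7.86 to 10.4). The uptake receptor gene Stra6 (ratio 0.104, 0.0822 to 0.129) and Rbp7 (ratio 0.156, 0.113 to 0.214), both among the 15 lowest genes, were lower. Of 30 Hox genes 6 were lower and 0 higher, with a median of -0.45 that stayed below 0 under all 4 other scalings, and Hoxc13, a regulator of hair keratins that is also in the hair list, was 84 and 22.4. On chromosome 15 from 101000001 to 102000000, which holds type II keratin genes, 10 of 30 genes were higher and 9 lower.

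Of the 24 basal and spinous keratinocyte markers 14 were higher in the library labelled KO, 2 lower and 7 below 0. A larger share of epidermis in the piece of skin would raise basal and spinous markers by about the same factor, but the interquartile range of the log2 ratios of these 24 markers was 1.9, against 0.45 for the fibroblast list, 4.25 times as wide. Over all tested genes that range was 0.65. The spread argues against 1 common factor for these 24 markers. It argues against more epidermis as the whole cause only if epidermis alone makes them, and the comparison was chosen after their values were seen. Simulated counting noise of independent fragments at this depth put at most 10 unchanged genes past the 2-fold rule in a pair, against 1698 observed. That argues against counting noise as well. A difference between the animals that the label does not name, and the genotype itself, stay open and cannot be separated with 1 library each.

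Rnf31 was not lower in the library labelled KO. Reads of Irf9 could add to its value, but removing the Irf9 fragments that even coverage would place on the 123 shared bases left FPKM values of 3.78 and 5.02 and a log2 ratio of 0.33. That is above 0, the outcome set in advance as counting against Irf9 reads. The bound assumed even coverage, which a table of 1 value per gene cannot show. Coverage 7.09 times the even level would make the libraries equal. This limit was weighed only after the value was seen, and the question was then left open. Deletion in keratinocytes alone or of a part of the transcript, and an exchange of the 2 labels, were not tested, since the table holds no values per exon or cell type.

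Of the 96 calls in the authors' deposited table, 34 were genes listed at 0 in the library labelled WT. Among genes with an FPKM of at least 1 in the library labelled KO and under 0.5 in the library labelled WT, 32 of the 123 listed at 0 were called (26.0%) in the authors' deposited table, against 0 of the 305 with a value above 0. The median FPKM in the library labelled KO was 1.79 and 1.69 in these sets. At an FPKM of 20 or more in the library labelled KO the authors' deposited table called 11 of 14 against 0 of 14. The cut of 0.5 was chosen after the results were seen. Just above it in the library labelled WT, the authors' deposited table called Il33 (0.528) and Rap1gap (0.725) but not others such as Fosl1 (0.792). These counts, 26.0% against 0, are consistent with an exact 0 favouring a call in a comparison of single libraries, a hypothesis drawn from the same table.

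Lower levels of hair shaft and pigment transcripts may reflect less RNA from the cells that build the hair shaft. All 8 measured shaft keratins of the hair list were lower (median -1.46), while 3 of 7 inner root sheath genes were lower (median -0.41). The Krtap family of hair shaft proteins, which no fixed list holds, should then be lower by 0.5 or more on the log2 scale. Its 53 measured genes had a median of -0.36 (range -1.57 to 6.39), with 8 lower and 4 higher. That median was at percentile 0 of expression-matched random lists, so the family was lower than genes of like expression. Under the 4 other scalings its median ran from -0.49 to -0.27. These medians lie between the value this hypothesis predicts and 0 and leave the hypothesis undecided. They do not bear on the pigment genes, for which the hypothesis was not tested.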
